A study of Arabidopsis thaliana with 6 samples.

How the data were processed

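Shoots of 3-week-old Arabidopsis seedlings were profiled on 6 Affymetrix ATH1 arrays. Of these, 3 carried line 14 of EBE-XVE and 3 carried the wild type, Col-0. EBE-XVE plants hold EBE under an estradiol-inducible promoter. EBE is locus AT5G61890, a transcription factor of the AP2/ERF family. Per the labels' protocols, seedlings spent 16 h in shaken liquid medium, and both genotypes then received 2 µM β-estradiol for 45 min. Groups and replicate numbers came from the sample titles, which call the replicates biological. All 6 arrays came from estradiol-treated seedlings, so there was no uninduced control, and EBE-XVE was represented by line 14 alone. Differences of that line from Col-0 therefore cannot be told apart from effects of induced EBE.

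The deposited values are on a log2 scale per probe set, and the submitters' processing notes name GCRMA and RMA without versions or roles. The log base is not given in the sources used here. It was taken as log2 from the range of the values, so every difference and fold below rests on that reading. The table held 22810 probe sets, of which 64 manufacturer's controls were left out and 22746 were tested. Scan dates and array batches are not given in the sources used here. The number of arrays limits the precision.

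Probe sets were named through the platform annotation and a reference gene table of assembly TAIR10.1, used for names only. A single gene symbol was listed for 13513 probe sets and several symbols for 503, while 8730 were unnamed here. Of the probe sets with 1 symbol, 13436 matched a locus, which gave 13286 loci. Probe sets with several symbols or none were tested but not given a gene name. Of 444 distinct loci on 20 gene lists fixed before the data were examined, only 64 had a named probe set, so 6 lists reached the minimum of 5 measured genes.

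EBE-XVE was compared with WT by limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a mean-variance trend, group as the only term, no further normalization and Benjamini-Hochberg adjustment. An adjusted p under 0.05, 2-sided, counted as a call. Gene lists were tested with camera at a preset correlation of 0.01, with 1 probe set per locus, that of the highest mean. Camera with an estimated correlation and fry were run beside it. The rule for named genes, fixed in advance, took EBE first. It then took probe sets of 1 gene that passed and whose 3 EBE-XVE values lay on one side of the 3 WT values, the 12 with the largest difference in each direction. Where fewer than 5 passed, the 5 with the smallest p in that direction were named and said not to pass. For each list with a camera call or at least 3 passing members it took up to 3 passing members, or else the 2 with the smallest p. DYL1, CYCD3;3, CDKB1;1 and BRC1 were to be given in any case, but no probe set was named for them here.

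Replicate numbers were checked as pairs. Deviations from the group means correlated across probe sets at 0.79, 0.54 and 0.58 for pairs 1, 2 and 3, so the numbers were treated as pairing the samples. EBE-XVE replicate 2 deviated as closely with WT replicate 3 (0.55), and EBE-XVE replicate 3 with WT replicate 2 (0.60). Replicate 1 therefore carried the pairing. No arrays held identical values. The closest arrays, WT replicates 2 and 3, differed with an SD of 0.20 log2 units.

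The fit was tested on simulated values with the spread and the replicate 1 shift of the real arrays and 200 changed probe sets among 22746. Without a block it recovered 29.9% of log2 changes of 1, 56.7% of changes of 2 and 86.4% of changes of 4, with 0 false calls. With replicate 1 as a batch block it recovered 59.7%, 95.5% and 100%, with 8 false calls. The replicate block recovered 47.8%, 97.0% and 100%, also with 8 false calls. Each simulated change was present on all 3 EBE-XVE arrays, so these shares do not hold for changes absent from 1 of them. Noise was drawn independently for each array from variances smoothed by the batch block fit. The shares may thus be too high for the real arrays. With the batch block, THI2.1 at -4.02 had an adjusted p of 0.55 in limma, and AT1G62500 at -2.03 had 0.43. Both genes were lower in every pair and neither was called. EBE, raised on 2 of the 3 arrays, was not called with the batch block. The alternatives fixed in advance were quantile normalization, median centring, eBayes without trend or with a robust prior, array weights, the omission of probe sets below the 40th percentile of mean signal, probe sets of 1 gene only, a replicate block, and the omission of each array. The omission of each array used no block. Without 1 of the replicate 1 arrays, the shift of the other thus stayed in 1 group and entered the difference, for single genes and for lists. For the counts, a 2-fold minimum, an adjusted p under 0.01 and an unmoderated statistic were also used. Fits with a batch block, with or without the array labelled EBE-XVE replicate 3, and fits on some replicates alone were added after the data were seen.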

Results

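The series was designed to find early target genes of EBE, 45 min after estradiol was given to EBE-XVE and WT seedlings. Shoot RNA was measured on 3 arrays per genotype. Median log2 signal was 5.38 and 5.47 on the replicate 1 arrays of EBE-XVE and WT, and 4.44 to 4.50 on the other 4 arrays. The root-expressed gene PYK10 stood at 12.14 and 12.26 on the replicate 1 arrays and at 8.58 to 9.21 on the others. The other measured root markers were not raised there. EXPA7 read 1.76 and 1.75 in replicate 1 against 2.11 to 2.13, and EXPA18 read 1.86 and 1.85 against 1.88 to 1.90. Both lay below the lower quartile of every array (2.50 to 2.67), too dim to speak for or against root tissue in replicate 1. The differences of replicate 1 in median signal and PYK10 ran across both genotypes alike.

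EBE itself was high on 2 of the 3 EBE-XVE arrays. Its log2 signal was 8.55 in EBE-XVE replicate 1 and 7.21 in replicate 2, against 4.26 and 2.98 in the WT arrays of the same number. The array labelled EBE-XVE replicate 3 read 3.19, beside 3.02 in WT replicate 3. Differences within pairs were thus 4.29, 4.23 and 0.17 log2 units. Group means were 6.32 ± 2.79 (SD, n = 3) in EBE-XVE and 3.42 ± 0.73 (SD, n = 3) in WT. The difference of 2.90 (SE 1.38) did not pass in limma (adjusted p = 1.00). It was 1.78 without EBE-XVE replicate 1 and 4.46 without the array labelled EBE-XVE replicate 3. The fit without EBE-XVE replicate 1 had no block, so WT replicate 1 kept its shift in 1 group only. With a batch block for replicate 1 and without the array labelled EBE-XVE replicate 3, EBE was 4.25 log2 units higher (SE 0.15), or 19.0-fold, with an adjusted p of 0.0316. That array was left out because of its EBE signal, so this p is not an independent test of EBE.

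**Figure D1:**
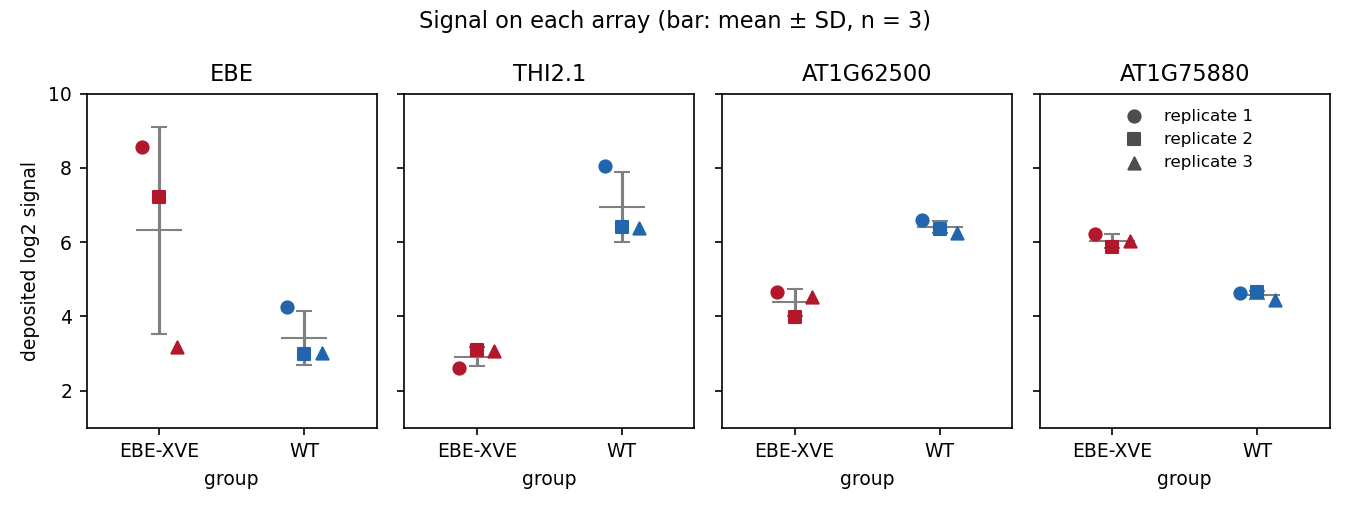
Deposited log2 signal (vertical axis) of EBE, THI2.1, AT1G62500 and AT1G75880 on each EBE-XVE and WT array, with symbols for replicate number and grey bars for the mean ± SD of 3 arrays. EBE reads 8.55 and 7.21 on EBE-XVE arrays 1 and 2 but 3.19 on the array labelled EBE-XVE replicate 3, and the other genes shown were chosen for their low p-values.

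The 3 lowest p-values among named genes belonged to genes with less signal in EBE-XVE, and no gene of this paragraph passed (adjusted p = 1.00 in limma for each). THI2.1, which encodes an antimicrobial thionin, read 2.92 ± 0.26 (SD, n = 3) in EBE-XVE and 6.94 ± 0.95 (SD, n = 3) in WT. Its difference was -4.02 (SE 0.52), and -5.42, -3.32 and -3.33 within the pairs, although EBE differed by only 0.17 in pair 3. A difference of the EBE-XVE line itself could not be told apart from an effect of EBE for any gene of this paragraph. AT1G62500, a lipid-transfer-like protein gene, differed by -2.03 (SE 0.31) and AT1G68875 by -1.95 (SE 0.33). AT1G12030 differed by -2.16 (SE 0.42), and AT2G28790, a thaumatin-like gene, by -1.32 (SE 0.34). The lowest p of all belonged to a probe set unnamed here, which differed by -2.60 (SE 0.29). In the other direction, AT1G75880, a GDSL-type lipase gene, was at 6.03 ± 0.18 (SD, n = 3) in EBE-XVE and 4.57 ± 0.12 (SD, n = 3) in WT, a difference of 1.46 (SE 0.26). AT2G05120, a nucleoporin gene, differed by 0.57 (SE 0.12) and AT5G18460 by 0.74 (SE 0.30). TRZ3, a tRNA 3′-processing enzyme, differed by 0.58 (SE 0.24), and UBP23, a ubiquitin-specific protease, by 0.49 (SE 0.21).

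Over all 22746 probe sets, limma called 0 higher and 0 lower in EBE-XVE. At an unadjusted p under 0.05 there were 79 probe sets, where chance gives 1137. The unmoderated statistic gave 107 and also no calls. The 3 EBE-XVE values lay wholly above or below the 3 WT values for 314 probe sets, or 1.38%. Chance gives 10% for exchangeable arrays, which these are not, since replicate 1 of both genotypes was shifted together. With the labels of pair 1, 2 or 3 swapped, a check added after the data were seen that keeps that shift, 519, 239 and 1822 probe sets were separated, and 63, 15 and 135 had an unadjusted p under 0.05. The replicate block and the batch block also gave 0 calls, with 462 and 515 probe sets at an unadjusted p under 0.05. Within replicates 2 and 3 alone, 3 probe sets were lower, those of THI2.1, AT5G33370 and AT2G20870, the last 2 named after their values were seen. In replicate 1, AT5G33370 read 1.70 in EBE-XVE and 1.69 in WT, and AT2G20870 read 2.84 and 3.09. With a replicate block, replicates 2 and 3 gave 276 higher and 161 lower, on 1 residual degree of freedom and with the variance taken wholly from the trend over all probe sets. Replicate 1 holds 1 array per genotype, so no test could be made within it.

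**Figure D2:**
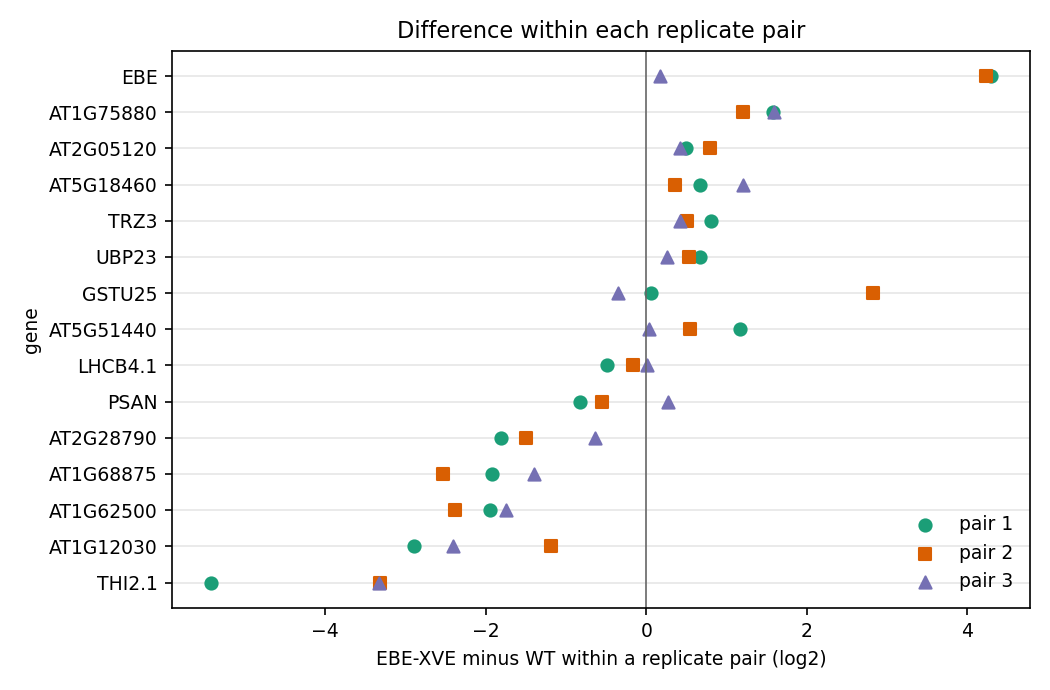
Difference between EBE-XVE and WT in log2 units (horizontal axis) within replicate pairs 1, 2 and 3 for EBE and the genes named by the fixed rule, 1 gene per line. EBE differs by 4.29 and 4.23 in pairs 1 and 2 and by 0.17 in pair 3, and THI2.1 lies below 0 in every pair.

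The 3 pairs were also set side by side, by a rule chosen after the data were seen. At least 2-fold differences in the same direction in every pair were found for 2 probe sets higher in EBE-XVE and 12 lower. The named ones among the lower were THI2.1, AT1G12030, AT1G62500, AT1G68875, AT5G55450 and AT3G28500, an acidic ribosomal protein gene that differed by -2.15 (SE 0.67). The higher ones were AT1G75880 and AT3G20370, the latter 3.74, 1.07 and 1.48 log2 units higher in pairs 1, 2 and 3. AT5G55450 differed by -1.38, -1.07 and -1.73. Between the group means AT3G20370 differed by 2.09, or 0.59 without EBE-XVE replicate 1, and AT5G55450 by -1.39, or -0.64 without WT replicate 1. These fits had no block, so the remaining replicate 1 array kept its shift in 1 group only. For AT3G20370 WT replicate 1 read 4.63, beside 2.57 and 2.58 in WT replicates 2 and 3. For AT5G55450 EBE-XVE replicate 1 read 8.58, beside 6.75 and 5.87 in EBE-XVE replicates 2 and 3. The values 0.59 and -0.64 thus mix the genotype difference with the replicate 1 shift. Swapping the labels in pair 1, 2 or 3 gave 5, 13 and 14 such probe sets, so the observed 14 did not exceed the swapped counts. Across probe sets, which are not independent, differences in pair 1 correlated with those in pair 2 at r = 0.16, and with those in pair 3 at r = -0.20. Pairs 2 and 3 correlated at r = -0.17.

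Among the gene groups fixed in advance, photosynthesis genes were lower and detoxification genes higher in EBE-XVE by camera at the preset correlation, and none of their members passed alone. Both calls were lost with an estimated correlation (adjusted p = 0.41 for each). Of 32 photosynthesis genes listed, 5 were measured, and all 5 were below WT. Their median was -0.22 and camera's adjusted p 5.2e-04, or 0.41 with an estimated correlation. PSAN, a photosystem I subunit gene, differed by -0.36 (SE 0.28) and LHCB4.1, a light-harvesting protein gene, by -0.22 (SE 0.18). Without WT replicate 1 these differences were -0.12 and -0.07, in a fit without a block, where EBE-XVE replicate 1 kept its shift in 1 group only. The photosynthesis medians within pairs 1, 2 and 3 were -0.48, -0.22 and 0.26, so the direction turned in the pair whose EBE-XVE array showed no raised EBE. The photosynthesis medians kept these signs under quantile normalization and median centring. The 69 plastid-encoded genes, a group chosen after the data were seen, had medians of -0.15, -0.16 and 0.13 in the same pairs, with the same signs under both scalings. Camera gave them an adjusted p of 0.25 with all arrays. With the batch block and without the array labelled EBE-XVE replicate 3 it was 1.2e-08, or 0.96 with an estimated correlation. The photosynthesis call was also lost without EBE-XVE replicate 1 (adjusted p = 0.26), EBE-XVE replicate 2 (0.33) or WT replicate 1 (0.78). Within replicates 2 and 3 alone the direction was up (adjusted p = 0.88), and over all alternatives the adjusted p ranged from 5.8e-07 to 0.92.

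Of 26 detoxification genes listed, 7 were measured, with 5 above WT and 2 below. Their median was 0.06 and camera's adjusted p 0.0154, or 0.41 with an estimated correlation. AT5G51440, listed as a small heat shock protein gene, differed by 0.58 (SE 0.30), with 1.17, 0.55 and 0.03 in pairs 1, 2 and 3, and by 0.31 without EBE-XVE replicate 1. GSTU25, a glutathione transferase gene, differed by 0.85 (SE 0.87), with 2.83 in pair 2 beside 0.07 and -0.35 in pairs 1 and 3, and by -0.19 without EBE-XVE replicate 2. The list medians within pairs 1, 2 and 3 were 0.07, 0.19 and -0.05, the last turning to 0.04 with quantile normalization. The detoxification call was also lost with quantile normalization (adjusted p = 0.0781), median centring (0.19), the dim probe sets left out (0.10) and the batch block (0.0624). It was also lost without EBE-XVE replicate 2, where the sign turned (0.40), without the array labelled EBE-XVE replicate 3 (0.27), and without WT replicate 1, where the sign also turned (0.81). Within replicates 2 and 3 alone the adjusted p was 0.0350, or 0.43 with an estimated correlation, and over all alternatives it ranged from 5.3e-05 to 0.81.

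The other 4 groups large enough to test had no camera call. Of 9 measured rapid stress regulators, 4 were above WT and 5 below, with a median of -0.01 although camera's direction was up (adjusted p = 0.70). With median centring 6 of the 9 were above WT, and the median turned to 0.01. That list was called higher within replicates 2 and 3 alone (adjusted p = 1.0e-04), without WT replicate 1 (0.0354) and with array weights (3.0e-05). With an estimated correlation these calls were lost (adjusted p = 0.43, 0.64 and 0.26). Its medians within pairs 1, 2 and 3 were -0.93, 0.46 and -0.09. Auxin response genes were above WT for 2 of 7, but for 5 of 7 with median centring. Cold and abscisic acid response genes were above WT for 1 of 5, or 2 of 5 under either other scaling, and were called lower with the batch block without the array labelled EBE-XVE replicate 3 (adjusted p = 0.0410, or adjusted p = 0.35 with an estimated correlation). Cell wall expansion genes were above WT for 2 of 5, or 3 of 5 with median centring. fry gave adjusted p-values of 0.86 or more for all 6 lists. Adjusted over the list alone, 0 members passed in any of the lists. Too few genes of the other lists had a named probe set to test them. Their other genes may lie among the 8730 probe sets unnamed here. Both measured cytokinin genes were below WT (median -0.68), as were both measured jasmonate genes (-1.12) and both measured ethylene genes (-0.05). All 3 measured regeneration genes (-0.05) and the only measured heat shock gene (-0.01) were also below WT. The jasmonate gene PDF1.2 differed by -1.09, -0.51 and -4.55 in pairs 1, 2 and 3, and OPCL1 by -0.44, -0.05 and -0.08. The cytokinin gene ARR16 differed by 0.66, -0.55 and -1.45, and ARR15 by -1.25, -1.43 and -0.07. Differences as small as those of the ethylene, regeneration and heat shock genes carry no direction. Of 4 cell cycle genes 2 were above WT, of 2 meristem genes 1, of 3 gibberellin genes 2, and of 2 genes of the ERF group that holds EBE 1. The only measured clock gene (0.14) and the only measured salicylate gene (0.35) were above WT. The clock gene, GI, differed by 0.49, -0.15 and 0.08 in pairs 1, 2 and 3. The salicylate gene, GRX480, differed by -0.37, -0.29 and 1.72, so its sign rested on pair 3. The bud dormancy and flower marker lists had 0 named probe sets, and of the root markers 3 of 20 were measured, with a median difference of 0.002.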

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

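The batch block, the fits on some replicates and the omission of the array labelled EBE-XVE replicate 3 together with the batch block were chosen after the data were seen. The counts of 0 higher and 0 lower probe sets held under 20 of 23 alternatives each, the replicate block and the omission of each array included (range 0 to 0). Array weights gave 15 higher and 24 lower, with weights of 8.41 and 7.11 on the replicate 2 arrays and 0.11 on each replicate 1 array, and the weight estimate did not converge. The batch block without the array labelled EBE-XVE replicate 3 gave 1 higher, EBE. Replicates 2 and 3 only gave 3 lower, and with a replicate block 276 higher and 161 lower, on 1 residual degree of freedom. The fits that left out each array in turn had no block. Without 1 replicate 1 array they thus kept the shift of the other in the difference. The difference of EBE was 1.78 to 4.46 in those fits, and did not pass in any of them. It passed at 4.25 with the batch block and without the array labelled EBE-XVE replicate 3. It also passed at 2.204 in replicates 2 and 3 with the replicate block, where its pairs differed by 4.23 and 0.17 and the variance came wholly from the trend over all probe sets, so that pass says nothing of the pairs' spread. The same arrays without the block gave an adjusted p of 0.91. Its adjusted p ranged from 4.1e-18 to 1.00 over the alternatives. The 2 list calls under the main setting stayed 2 with the replicate block, and no other call changed under that block with all arrays. The number of lists was 1 with quantile normalization, with or without the batch block, with median centring, with the dim probe sets left out, with the batch block and with replicates 1 and 2 only. It was 3 with array weights, 0 with an estimated correlation and 0 with fry, and 0 to 2 when each array was left out. With an estimated correlation no list passed in any of the fits. Over 20 single-gene results and 397 alternatives, 1 reversed: GSTU25, at -0.19 to 1.37 when each array was left out, the low end without EBE-XVE replicate 2. In 24 others a gene that had not passed did so, in 23 of them with array weights or within replicates 2 and 3. AT2G05120 has no value with the dim probe sets left out. For these shifts the cause was not tested. Signal over background was not measured per probe set, so what dim probe sets could show stays unknown.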

Other observations

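The tests of explanations in this part were chosen after the results were seen, apart from the counts over other splits of the arrays. Replicate 1 of both genotypes differed from the other arrays in plastid-encoded genes, in some single genes and in control probe sets. Plastid-encoded genes were lower there, with a median of -1.74 over 69 genes, and -2.38 after quantile normalization. Among them the difference of replicate 1 from the other arrays was -4.15 for atpH, -3.99 for atpI, -3.84 for atpF and -3.21 for psaI. OSM34, an osmotin gene, was 6.20 log2 units higher in replicate 1 (5.66 after quantile normalization), and ChiC, a chitinase gene, 4.98 higher (4.49). The 25S rRNA control read 5.74 in WT replicate 1, below 7 in EBE-XVE replicate 1 and 10.10 to 11.05 on the others. The 3′ minus 5′ difference of the actin control was 1.05 and 1.17 on the replicate 1 arrays against 1.56 to 1.83 on the others, and that of GAPDH was 0.31 and 0.70 against 0.75 to 1.09.

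Of 48 genes on a low-oxygen response list, the 23 with a named probe set moved apart between pairs. The list was written from general knowledge after 3 of its genes had been seen. In pair 2, 20 of the 23 were higher in EBE-XVE, 16 of them at least 2-fold, with a median of 1.51. In pair 3, 21 of the 23 were lower, with a median of -0.52, but only 5 were at least 2-fold lower and 2 were at least 2-fold higher. In pair 1, 12 were higher and 11 lower, with a median of 0.01. The signs in pairs 2 and 3 held under quantile normalization (1.56 and -0.50) and median centring (1.46 and -0.49). AT3G10040 differed by 4.75 in pair 2 and -0.88 in pair 3, and AT4G10270 by 3.23 and -5.48. With all arrays, camera gave this list p = 1.4e-05 without a block and p = 0.0058 with the batch block, or 0.24 and 0.47 with an estimated correlation. With the batch block and without the array labelled EBE-XVE replicate 3, the values were 7.1e-09 and 0.23.

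The replicate 1 arrays differed at least 2-fold from the rest for 5137 probe sets. Of these, 38.4% stayed 2-fold apart after quantile normalization, so a different overall scale may account for part of them. As deposited, 4734 were higher and 403 lower in replicate 1, and after that normalization 1571 were higher and 1350 lower, 947 of the lower ones not 2-fold apart before. The plastid-encoded median of -1.74 lay below the central 95% of 10000 lists matched on mean signal (0.33 to 0.66). The group was chosen after the data were seen, so this is no independent test. A different capture of RNA with short or no poly(A) tails could give such a shift, but the comparison cannot decide on it. A biological difference between the seedling batches stays open and was not tested.

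The array labelled EBE-XVE replicate 3 showed EBE at the WT level. Its 18 hybridisation controls had a median difference of 0.0089 from the other 3 arrays of replicates 2 and 3. These values were deposited after processing, which can even out brightness between arrays. They therefore cannot exclude a dim array. Across the tested probe sets, the array labelled EBE-XVE replicate 3 correlated at 0.9928 and 0.9921 with WT replicates 2 and 3. EBE-XVE replicate 2 correlated with them at 0.9927 and 0.9924. These values argue against a failed array. Against a wild-type sample under the EBE-XVE label, THI2.1 read 3.06 on that array, beside 2.62 and 3.09 on the other EBE-XVE arrays and 6.38 to 8.04 in WT, and AT1G62500 read 4.51, beside 4.65 and 3.98 and 6.26 to 6.60. These genes were picked after their values were seen, and of all 63 probe sets at least 2-fold lower in pairs 1 and 2, only 12 were so in pair 3, with 5 at least 2-fold higher and a median of 0.14. Of 37 probe sets at least 2-fold higher in pairs 1 and 2, EBE aside, 2 were so in pair 3 and 9 were at least 2-fold lower, with 35 below 0 and a median of -0.54. The exact binomial p, one-sided for the direction of pairs 1 and 2, was 0.0717 for the 63 lower probe sets and 0.9941 for the 37 higher ones. It takes probe sets as independent, which they are not. An EBE-XVE sample that did not respond would also lack changes that follow EBE. A wild-type sample and a sample without response therefore both stay open.

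For the low-oxygen genes, the medians did not follow the level of EBE across the pairs. The pair 3 median of -0.5231 lay outside the central 95% of matched lists (-0.16 to 0.10), although EBE was not raised there. In pair 1, with EBE raised, the median of 0.01 lay inside. Matched lists take genes as independent, and each pair holds 1 array per genotype. These ranges thus do not measure the spread between samples, and the level of EBE stays open as a cause. An array-wide shift within pairs is argued against, since 2 of the 3 medians lay outside. Without the 3 genes seen beforehand the medians were -0.03, 1.40 and -0.51. Those genes were at least 2-fold higher in pairs 1 and 2 but not in pair 3. Leaving them out thus does not make the list independent of these data. A candidate explanation, not tested, is that oxygen supply in the shaken liquid medium differed between cultures.

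The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 higher and 0 lower probe sets, and the highest of the other splits 0. At an unadjusted p under 0.05 the 4 splits that hold both replicate 1 arrays together gave 1952 to 4676 probe sets, against 79 for the real split, which points to replicate 1 as a structure of the samples. With replicate 1 as a batch block the real split gave 515.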
